A study of Danio rerio with 6 samples.

How the data were processed

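RNA was measured in whole zebrafish larvae at 5 days after fertilisation. The samples were 3 libraries of pdcd7 mutants and 3 libraries of wild-type siblings, and the labels put all 6 in batch 1. The labels name the mutant line pdcd7/cx20, allele pd1215, and leave open what cx20 stands for. They state that RNA came from 40 larvae with 3 replicates, and leave open whether 40 is the number per replicate. Per the labels' protocols, the RNA was treated with DNase and made into libraries with a stranded kit that selects polyadenylated mRNA. The libraries were sequenced as read pairs. Nothing in the labels says that the replicates came from separate clutches. The p-values therefore measure the spread between these libraries only, which may be technical.

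The authors deposited raw counts of read pairs per gene, 1 table per library, with no normalization. Per the file headers, the counts were made with featureCounts 1.6.3 over the exons of Ensembl gene models of build GRCz11, annotation release 115. The headers show a paired, strand-specific setting (2), so reads of antisense genes were told apart, and no option that counts reads with several alignments. Near-identical copies such as crystallin, haemoglobin, snRNA and 5S rRNA genes can therefore lose reads, and their counts per gene are uncertain. Reads in introns were not counted, so intron retention was not measured here. Per the submitters' processing notes, Trimmomatic 0.38, STAR 2.7.11 and Subread 1.6.3 were also used.

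Each table held the same 32520 gene IDs, and each row named a gene. Symbols were taken from a table of IDs and symbols that matched 29201 IDs (89.8%). The symbols are printed as that table gives them, often in the human style. Of the symbols, 1806 stand on more than 1 ID, and for such genes the ID is added. Coordinates are those of the files, build GRCz11. The deposited counts summed to between 75122088 and 87110177 per library. A count of 0 allows up to 3 counts in a library, which is 0.0344 to 0.0399 CPM (counts scaled to library size). These floors cover counting error only.

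The main test was edgeR's quasi-likelihood F-test (edgeR 4.0.16, R 4.3.3), two-sided, with genotype as the only term. Low counts were removed with filterByExpr, libraries were scaled with TMM factors, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Log2 fold changes are mutant minus wild type. CPM values use the TMM-scaled library sizes, and errors are SDs over n = 3 libraries unless marked SE. On counts simulated from the real means and library sizes, with 200 of the genes changed, the mutant and wild-type comparison recovered 64.0% of genes changed 1.25-fold, 90.0% at 1.5-fold, 92.0% at 2-fold and 100% at 4-fold. In that simulation over 24084 genes, 3.4% of the calls were false. These rates are for few changed genes and may not hold for the real data, where 68.9% of tested genes were called.

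Gene lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2. The preset correlation was 0.01, and adjustment was over the 51 lists, each with at least 5 tested genes. Camera with an estimated correlation and fry were run beside it. The lists were fixed before the data were examined and cover pathways and markers of the tissues of a larva. In bulk whole larvae they measure transcripts of a tissue, not cells. Of 1580 list entries, 1158 matched a symbol exactly, 286 after the paralogue letter was dropped, 38 through a synonym, and 98 were not matched. Synonyms came from a RefSeq table of another assembly (GRCz12tu), used for names only. Minor introns were to be found from the genome sequence. No genome was used here, so a list of genes whose human relatives carry minor introns, written from general knowledge, stands alone.

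The text names PDCD7 and, among called genes with a mean of at least 5 CPM in the higher group, no overlap between groups and a symbol that is not a code, the 8 largest rises and 8 largest falls. It adds the 4 further risen and 4 further fallen genes with the smallest p. For each list it draws on the 4 members with the smallest adjusted p in the majority direction and the 1 going the other way. The rule for the largest rises passed over 5 genes with a code for a name, and the other parts passed over 0.

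For calls along the genome, the share of called genes on chromosome 7 was set against all other chromosomes, with p from 10000 random circular shifts of the gene order. On simulated calls this step found a planted excess and no excess where none was planted. The alternatives were other scalings, 2 other filters, DESeq2 1.42.0, limma-voom, the replicate number as a block, each library left out in turn, other thresholds and other windows. Figures were drawn with matplotlib 3.10.9.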

Results

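Polyadenylated RNA was profiled in whole zebrafish larvae, 5 days after fertilisation, from pdcd7 mutants and their wild-type siblings, with 3 libraries in each group. PDCD7 is a protein of the U11 particle of the minor spliceosome, which removes the rare U12-type introns. The series compares the 2 genotypes at 1 age. The labels name the mutants pdcd7/cx20, so if cx20 is a further locus, the differences cannot be assigned to pdcd7 alone. Library totals were 75993728, 80204984 and 87110177 counts in mutants and 75122088, 80051408 and 80871977 in siblings. The 10 most abundant genes took 8.04% to 8.19% of the counts in mutants and 7.23% to 7.42% in siblings. Mitochondrial genes took 3.45% to 3.54% and 3.12% to 3.22%.

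Libraries grouped by genotype. The first principal component held 86.0% of the variance and separated the groups. Pearson correlations of log2 CPM across genes, which are not independent replicates, were 0.996 to 0.997 within groups and 0.964 to 0.970 between them. Replicates of a group differed beyond counting noise, with chi-square values per degree of freedom of 4.75 to 6.65, so no library was a copy of another. The coefficient of variation that edgeR terms biological was 4.22%. It covers the spread between these libraries only, which may be technical.

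The gene pdcd7, which the labels name for the mutant line, was checked first. PDCD7 (ENSDARG00000038976, chromosome 7, 13684012 to 13737618, plus strand) measured 21.8, 19.6 and 20.5 CPM in the mutant libraries and 14.8, 15.0 and 15.3 CPM in the siblings. Its transcript was therefore 1.37-fold higher in mutants (log2 0.46 ± 0.05 SE, adjusted p = 7.92e-08 in edgeR). The counts do not show the mutated base, so this value neither places nor excludes the lesion.

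The question the design poses is which transcripts differ between pdcd7 mutants and their siblings. Of 24248 genes tested, 8402 were higher and 8294 lower in mutants, 68.9% in all (adjusted p in edgeR). The balance depended on the scaling, with 9321 higher and 7429 lower under upper quartile scaling and 10006 and 6827 with library size only. Changes of at least 1.5-fold numbered 2588 and 2700, and those of at least 4-fold 151 and 346. The 2 groups did not overlap for 17492 genes (72.1%), where chance gives 10%. With so small a spread between libraries, calls include many small changes. A test against a 1.5-fold change, chosen after seeing the data, called 1400 genes higher and 1764 lower.

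Among genes with at least 5 CPM, no overlap and a symbol that is not a code, the largest rise was that of a U2 snRNA gene (ENSDARG00000082321), an RNA of the major spliceosome, at 5.40 ± 0.163 CPM in mutants and 0.0738 ± 0.0264 in siblings. It was followed by arf4b, a small GTPase gene, at 20.5 ± 2.11 against 1.80 ± 0.123 CPM, and bmb, a gene of nuclear envelope fusion, at 10.7 ± 0.909 against 1.14 ± 0.205. The mucin gene muc5.3 rose 7.48-fold, the extracellular matrix gene emilin3a 7.01-fold, the CREB coactivator gene crtc1b 6.51-fold and the secreted phosphoprotein gene scpp5 6.21-fold. EDC4, a scaffold of mRNA decapping, rose 6.04-fold from 43.0 ± 0.351 to 260 ± 7.44 CPM, with the smallest p of all genes (adjusted p = 3.97e-19). The genes that rose with the next smallest p were ice1, a subunit of the little elongation complex (5.42-fold), ppp2r2ba, a regulatory subunit of protein phosphatase 2A (5.71-fold), MYSM1, a histone H2A deubiquitinase (4.63-fold), and XPO7, a nuclear export receptor (4.41-fold). By that rule, each of these genes was higher in 3 of 3 mutant libraries than in any sibling library.

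By the same limits, the 8 largest falls were all genes of the lens. CRYAA, the lens chaperone alpha A crystallin, measured 0.480 ± 0.515 CPM in mutants and 35.3 ± 6.78 in siblings, 73.7-fold lower (log2 -6.20 ± 0.48 SE, adjusted p = 3.81e-04 in edgeR). The crystallin genes crybb1l1, CRYBB1, cryba1b, crybgx and cryba1l1 were lower by 57.0-, 49.5-, 45.3-, 37.6- and 35.7-fold. MIP (ENSDARG00000013963), the lens water channel, was 46.1-fold lower, and the protease gene CAPN3 (ENSDARG00000041864) 39.9-fold lower. Mutant replicate 2 kept more of these transcripts than the other mutant libraries, with 1.07 CPM of CRYAA against 0.154 and 0.211. Without that library the log2 change of CRYAA was -7.57, of crybb1l1 -7.61, of CRYBB1 -7.45, of MIP -6.44 and of cryba1b -6.67. It was -6.38 for CAPN3, -6.10 for crybgx and -6.03 for cryba1l1, and all 8 calls stood. The genes that fell with the smallest p were SLC15A1 (ENSDARG00000044528), the gut peptide transporter, at 40.7 ± 1.57 against 204 ± 7.08 CPM, and pm20d1.1, smim24 and gpx4a. These last were lower by 5.17-, 3.99- and 3.80-fold.

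**Figure D1:**
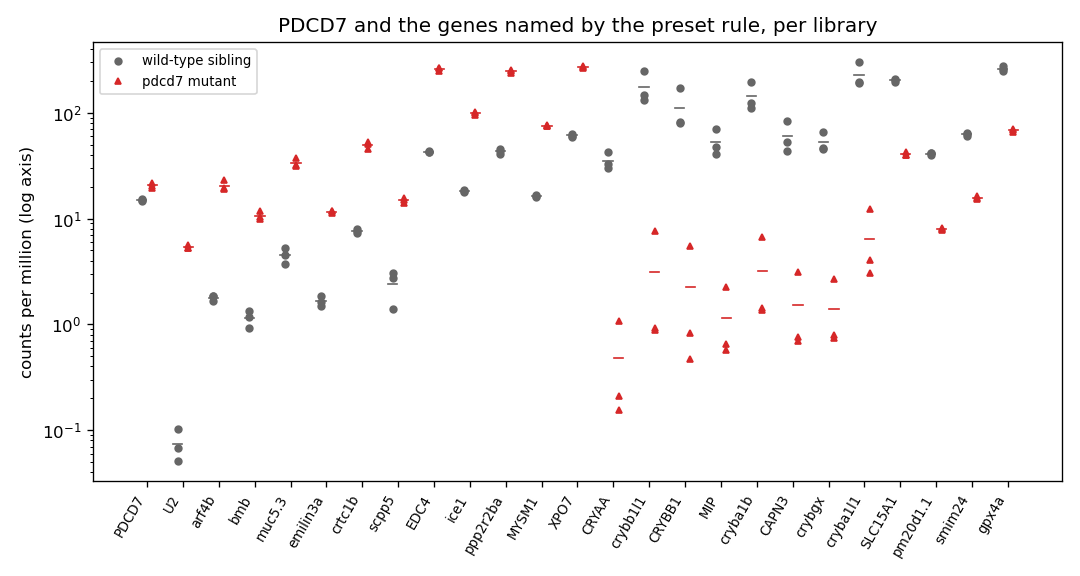
CPM on a log axis for PDCD7 and the 24 genes named by the preset rule, 1 point per library, with circles for wild-type siblings, triangles for pdcd7 mutants and short lines for group means (n = 3). No gene shows overlap between groups, which the rule required of all but PDCD7. The lens genes in mutants spread most, with mutant replicate 2 on top.

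Of 51 gene lists, 11 lay higher and 15 lower in mutants than other genes by camera with its preset correlation. With an estimated correlation 0 lists passed, the lowest adjusted p being 0.24, and 4 had an unadjusted p under 0.05. Fry, which asks whether members move 1 way on balance and not whether they differ from other genes, called 43. With 68.9% of tested genes called, it also passed lists that camera did not, such as slow muscle (adjusted p = 0.000106 by fry and 0.286 by camera). Its count therefore does not show that lists stand apart. Counts of called members adjusted over the list alone were the same as those over all genes, except in 5 lists. Those were 20 higher for the unfolded protein response, 17 higher for the amino acid and ATF4 response, 27 higher for ribosomal proteins, 24 higher for neural progenitors and 6 lower for erythrocytes.

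Genes of the major spliceosome rose together. Of 54 measured, 50 rose and 2 fell, with a median log2 change of 0.49 (adjusted p = 1.47e-11 by camera). With an estimated correlation the adjusted p was 0.27. EFTUD2, a GTPase of the U5 particle, rose by log2 0.81 ± 0.03 SE, SNRPE, an Sm core protein, by 1.15 ± 0.05, and SNRNP200, the U5 helicase, by 0.66 ± 0.03, while SF3B1, of the U2 particle, fell by 0.35 ± 0.03. Of 14 proteins of the minor spliceosome, 5 rose and 2 fell, which did not set the list apart (adjusted p = 0.313). In it, cenatac rose by log2 1.55 ± 0.04 SE, ZRSR2 by 0.66 ± 0.06 and armc7 by 0.59 ± 0.09, and rbm48 fell by 0.47 ± 0.07. Of 40 SR proteins and splicing regulators 22 rose and 8 fell (adjusted p = 0.067). That list passed with upper quartile scaling (adjusted p = 0.0303), library size only (0.0181), DESeq2 (0.0189), limma-voom (0.0344) and without sibling replicate 3 (0.0441), and its highest value over the alternatives was 0.12. Of 12 factors of nonsense-mediated decay 7 rose and 4 fell (adjusted p = 0.493).

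Genes listed as carrying minor introns moved both ways, more often up. Of 101 measured, 58 rose and 31 fell, 35 rose by at least 1.5-fold and 7 fell by as much. The median log2 change was 0.23 (adjusted p = 0.00504 by camera). With an estimated correlation the adjusted p was 0.319. Members called higher made up 57.4% of the list and 34.6% of other tested genes (two-sided Fisher's exact test over genes, which are not independent replicates, p = 2.93e-06), and those called lower 30.7% and 34.2% (p = 0.528). XPO7 rose by log2 2.14 ± 0.03 SE, the kinase gene MAPK8 (ENSDARG00000031888) by 1.94 ± 0.04 and the stress kinase gene MAPK14 (ENSDARG00000000857) by 1.48 ± 0.04. MLST8, a subunit of the TOR kinase complexes, fell from 23.5 CPM in siblings (adjusted p = 1.97e-13 in edgeR).

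Genes of DNA replication and mitosis formed the most uniform rise. Of 67 measured, 64 rose and 0 fell at the threshold, with a median log2 change of 0.58 (adjusted p = 3.55e-15 by camera, and adjusted p = 0.27 with an estimated correlation). UHRF1, a partner of the maintenance DNA methyltransferase, rose by log2 0.93 ± 0.03 SE, TYMS, which makes thymidylate, by 1.02 ± 0.05, and PCNA, the sliding clamp, by 0.64 ± 0.03. Of 31 neural progenitor genes 23 rose and 2 fell (median 0.27, adjusted p = 0.000221, and adjusted p = 0.319 with an estimated correlation). CCND1, a G1 cyclin gene, rose by 0.79 ± 0.03 and sox19a by 0.48 ± 0.03, and DLD, a Notch ligand gene, fell by 0.21 ± 0.03.

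The unfolded protein response and heat shock lists were higher, and the amino acid and ATF4 list did not stand apart. Of 25 genes of the unfolded protein response 19 rose and 1 fell (median 0.62, adjusted p = 3.97e-06, and adjusted p = 0.27 with an estimated correlation). HSPA5, the main chaperone of the endoplasmic reticulum, rose by log2 1.38 ± 0.03 SE and HYOU1 by 1.36 ± 0.03, and HERPUD1 fell by 0.24 ± 0.04. Of 22 heat shock genes 16 rose and 2 fell (adjusted p = 0.000269, and adjusted p = 0.27 with an estimated correlation), among them HSPD1, the mitochondrial chaperonin, by 1.12 ± 0.04, and HSF2 fell by 0.38 ± 0.04. In the amino acid and ATF4 list 16 of 33 rose and 11 fell (adjusted p = 0.506), with ATF3 up by 1.02 ± 0.04 and slc3a2a down by log2 -0.77 ± 0.03.

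Transcripts of the lens and the digestive organs were lower. Of 52 lens genes 50 fell and 1 rose, with a median log2 change of -3.84 (adjusted p = 3.49e-14 by camera, and adjusted p = 0.355 with an estimated correlation). Summed over the list, lens genes held 326 ± 92.2 CPM in mutants and 4940 ± 912 in siblings, and mutant replicate 2 held 429.8 CPM against 295.3 and 253.3. The exception lim2.2 was higher by log2 0.39 ± 0.15 SE (adjusted p = 0.0310 in edgeR). Its call ended without mutant replicate 2 (0.34), sibling replicate 2 (0.30) or sibling replicate 3 (0.37) and in DESeq2 (0.39). Of 31 exocrine pancreas genes 27 fell and 1 rose (median -3.09, adjusted p = 1.56e-09, and adjusted p = 0.355 with an estimated correlation). The zymogen granule protein genes cuzd1.2 and cuzd1.1 changed by log2 -1.65 ± 0.08 SE and -1.85 ± 0.10 and RBPJL, an acinar transcription factor gene, by -1.55 ± 0.17, while amy2al1, an amylase gene, rose by 0.60 ± 0.11.

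Of 44 enterocyte genes 38 fell and 4 rose (median -1.41, adjusted p = 2.45e-11, and adjusted p = 0.27 with an estimated correlation). SLC5A1, the sodium-glucose transporter, changed by log2 -1.42 ± 0.03 SE, TM4SF4 by -1.41 ± 0.04 and ANPEP (ENSDARG00000036809), an aminopeptidase gene, by 0.52 ± 0.03. Of 19 genes of lysosome-rich enterocytes and the ileum 13 fell and 2 rose (median -0.39, adjusted p = 0.000523, and adjusted p = 0.27 with an estimated correlation), with CUBN, the endocytic receptor cubilin, at -0.87 ± 0.03 and tmigd1 at 0.21 ± 0.06. Of 44 lysosome genes 26 fell and 9 rose (adjusted p = 0.00507, and adjusted p = 0.319 with an estimated correlation). The cathepsin gene ctsbb, on both lists, changed by -2.70 ± 0.07, and ctsla by 0.30 ± 0.03. Of 52 hepatocyte genes 47 fell and 1 rose (median -0.94, adjusted p = 3.55e-15, and adjusted p = 0.24 with an estimated correlation). TTR, the thyroid hormone carrier, changed by -1.64 ± 0.04 and c9, a complement gene, by -1.32 ± 0.04. The riser hp, near the detection floor at 0.164 CPM in siblings (log2 0.99 ± 0.38 SE), lost its call without mutant replicate 2 (0.82), sibling replicate 2 (0.69) or sibling replicate 3 (0.73), and in DESeq2 (0.97), and stood at 1.73 without sibling replicate 1.

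Photoreceptor, inner retina, neuron and hair cell lists were also lower. Of 69 photoreceptor genes 56 fell and 6 rose (median -1.06, adjusted p = 2.61e-12, and adjusted p = 0.27 with an estimated correlation). PDE6C, the cone phosphodiesterase, measured 245 CPM in mutants and 641 in siblings (log2 -1.39 ± 0.03 SE), and AIPL1, its chaperone, rose by 0.52 ± 0.09. Of 33 inner retina and pigment epithelium genes 18 fell and 7 rose (adjusted p = 0.0414, and adjusted p = 0.27 with an estimated correlation), rx2 and cabp5b changing by -1.01 ± 0.06 and -1.21 ± 0.07 and STRA6 by 0.42 ± 0.05. That call ended without mutant replicate 3 (adjusted p = 0.0510), sibling replicate 1 (0.0504) or sibling replicate 3 (0.0547), with the replicate block (0.0512) and with the filter of 1 CPM (0.0540). Of 57 neuron genes 43 fell and 2 rose (median -0.31, adjusted p = 1.21e-07, and adjusted p = 0.27 with an estimated correlation), CAMK2A at -0.98 ± 0.04 GAD2 at -0.73 ± 0.03 and tubb5 at 0.27 ± 0.03. Of 33 hair cell genes 20 fell and 6 rose (adjusted p = 0.0217, and adjusted p = 0.426 with an estimated correlation), pvalb8 at -1.18 ± 0.03 and the myosin gene MYO7A (ENSDARG00000044632) at 1.13 ± 0.04. Of 30 glia and myelin genes 16 fell and 10 rose (adjusted p = 0.129, and 0.000725 in DESeq2, with up to 0.154 over the alternatives). The myelin genes mbpa and plp1b stood at log2 -1.38 ± 0.04 SE and -1.24 ± 0.04, and the fatty acid binding protein gene FABP7 (ENSDARG00000007697) at 0.54 ± 0.04.

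Immune and clock lists were lower with an exception. Of 29 interferon response genes 17 fell and 2 rose (median -0.81, adjusted p = 0.00452, and adjusted p = 0.664 with an estimated correlation), ifi44a1 at -3.08 ± 0.19 SE and ifit10 at -2.26 ± 0.22, and mxc at 0.99 ± 0.14. Of 47 neutrophil and macrophage genes 31 fell and 5 rose (adjusted p = 0.000124, and adjusted p = 0.27 with an estimated correlation), CORO1A at -0.68 ± 0.05 and mmp13a at 0.70 ± 0.11. Of 20 lymphocyte and thymus genes 14 fell and 4 rose (adjusted p = 0.0451, and adjusted p = 0.417 with an estimated correlation), RAG1 at -0.91 ± 0.06 and ccl25b at 0.45 ± 0.04. That call ended without mutant replicate 3 (adjusted p = 0.0510) or sibling replicate 2 (0.0509), in DESeq2 (0.218), in limma-voom (0.0690) and with the filter of 1 CPM (0.0736). The inflammation and acute phase list went the other way, with 16 of 25 higher and 3 lower (median 0.57, adjusted p = 0.00475, and adjusted p = 0.27 with an estimated correlation), leap2 at 1.28 ± 0.05 and c3a.1 at -0.67 ± 0.04. Of 33 circadian clock genes 27 fell and 2 rose (median -0.40, adjusted p = 3.55e-06, and adjusted p = 0.27 with an estimated correlation), BHLHE40 at -0.69 ± 0.03 and bmal2 at 0.96 ± 0.05. Of 12 glucocorticoid targets 9 fell and 1 rose (adjusted p = 0.00475, and adjusted p = 0.319 with an estimated correlation), FKBP5 at -0.63 ± 0.03 and nfkbiaa at 0.33 ± 0.05. The PER1 genes ENSDARG00000056885 and ENSDARG00000012499, at -0.56 and -0.36, are on this list and the clock list, so these lists are not separate results.

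Fibroblast and matrix, cartilage, epidermis and cholesterol synthesis lists were higher. Of 30 fibroblast and matrix genes 26 rose and 2 fell (median 0.41, adjusted p = 3.38e-06, and adjusted p = 0.27 with an estimated correlation), COL6A3 at log2 0.74 ± 0.03 SE, MMP2 at 0.70 ± 0.03 and a fibronectin gene, FN1 (ENSDARG00000006526), at -0.37 ± 0.04. Of 35 cartilage genes 21 rose and 6 fell (adjusted p = 0.00226, and adjusted p = 0.426 with an estimated correlation), hapln1a at 1.15 ± 0.03 and prg4b at -1.53 ± 0.05. Of 40 epidermis genes 24 rose and 7 fell (adjusted p = 0.0133, and adjusted p = 0.27 with an estimated correlation), cldne at 0.44 ± 0.03 and krt92 at -0.83 ± 0.03. Of 26 cholesterol synthesis genes 16 rose and 4 fell (adjusted p = 0.0414, and adjusted p = 0.629 with an estimated correlation), IDI1 at 0.64 ± 0.03 and insig1 at -0.78 ± 0.05. That call ended without mutant replicate 1 (adjusted p = 0.0714), sibling replicate 1 (0.0623) or sibling replicate 3 (0.0684), in DESeq2 (0.0961) and with library size as the only scaling (0.0551).

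**Figure D2:**
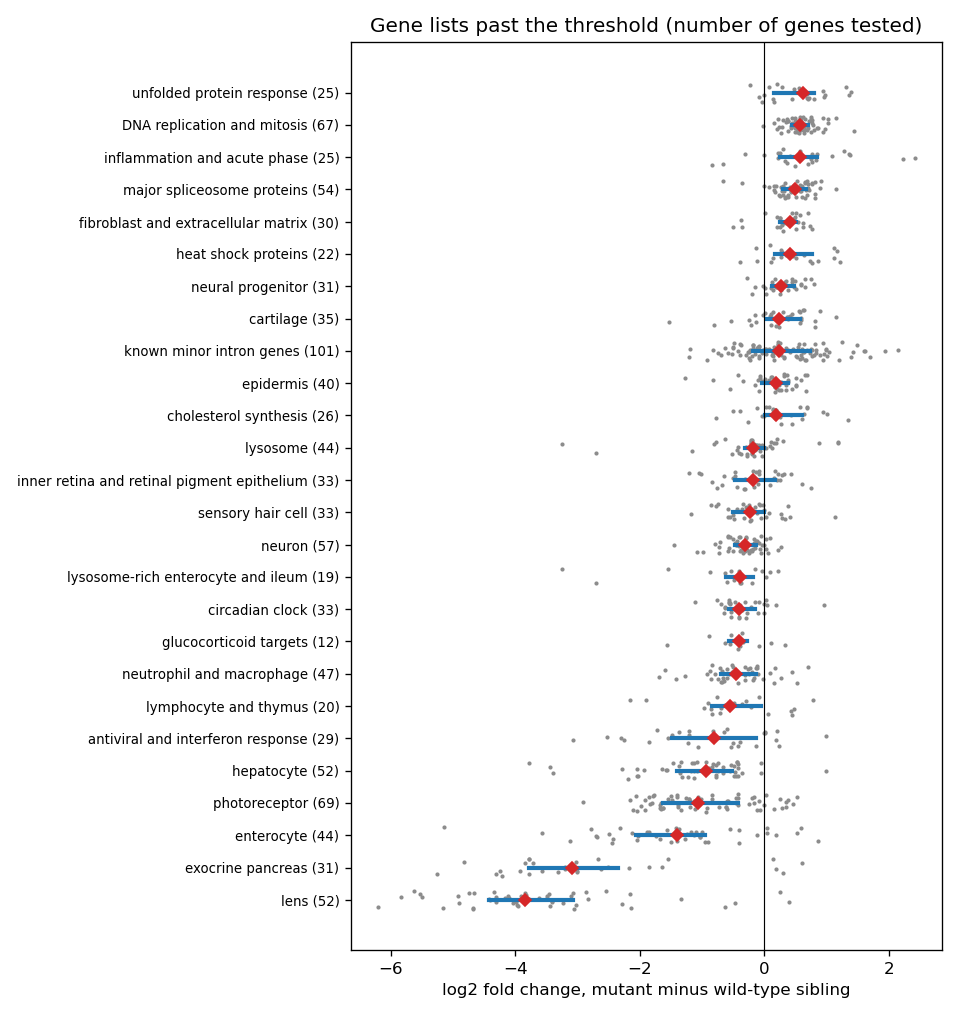
Log2 fold changes of the members of the 26 gene lists past the preset camera threshold, 1 grey point per gene, with the median as a red diamond and the middle 50% as a blue bar; the number of genes tested follows each name. Medians run from -3.84 for the lens to 0.62 for the unfolded protein response.

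Muscle, heart, bone, vessel and blood lists did not stand apart. Of 53 fast muscle genes 22 rose and 17 fell, with a median of 0.00 (adjusted p = 0.651), and the list held 66500 ± 1210 CPM in mutants and 67000 ± 1560 in siblings. The counts higher and lower were 4 and 1 of 13 for slow muscle, 5 and 8 of 24 for heart, 10 and 3 of 19 for notochord and 8 and 7 of 19 for bone. They were 13 and 14 of 40 for endothelium, 6 and 7 of 24 for erythrocytes, 10 and 10 of 35 for kidney, 11 and 18 of 36 for ionocytes and 19 and 14 of 41 for pigment cells. For goblet cells they were 7 and 2 of 12, with AGR2, a disulfide isomerase of mucus cells, at log2 1.32 ± 0.04 SE and itln3 at -1.05 ± 0.11. Endocrine pancreas and enteroendocrine genes gave 4 and 12 of 31, connexins 6 and 11 of 27, motile cilia 1 and 10 of 30, hatching gland and pharyngeal endoderm 6 and 3 of 11, and yolk and maternal genes 3 and 0 of 8. The notochord list passed with the filter of 1 CPM (adjusted p = 0.0378, otherwise up to 0.137), and motile cilia without a filter (0.0463, otherwise up to 0.461). Nuclear genes of oxidative phosphorylation gave 17 and 30 of 93 and mitochondrial genes 5 and 0 of 13. Ribosomal protein genes gave 29 and 16 of 95, but the name pattern also took 11 genes of S6 kinases. Without these, chosen after seeing the data, they gave 26 and 11 of 84 (unadjusted p = 0.214 by camera). Median and camera direction differed in sign for heart, erythrocytes and kidney, among the lists described here, all short of the threshold, and mean and direction for heart, pigment cells and the amino acid list.

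Siblings and mutants can differ at loci linked to the mutation, so calls near PDCD7 were counted. On chromosome 7, 893 of 1255 genes (71.2%) were called, against 15800 of 22990 (68.7%) on other chromosomes (p = 0.42, two-sided permutation by circular shifts). Within 10 Mb of PDCD7 the share was 249 of 348 (71.6%, permutation p = 0.49). The sign of these differences, 2.43 and 2.82 percentage points, turned with no filter on low counts (-0.13 and -6.31) and in DESeq2 (-0.33 and -6.61), and within 5 Mb it was -1.79, none past the threshold. For calls of at least 2-fold, a threshold chosen after seeing the data, chromosome 7 held 145 of 1255 genes against 8.40% elsewhere (permutation p = 0.02) and the 10 Mb window 53 of 348 (permutation p = 0.023). Among the genes named above, muc5.3 and crybgx lie on chromosome 7, starting at 72291181 and 34222433, both outside the 10 Mb window.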

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

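The tests against a 1.5-fold change, the 2-fold thresholds and the ribosomal list without S6 kinases were chosen after seeing the data. The direction and call of PDCD7, the count of called genes, the count of lists and the minor intron call held under the other scalings, filters and tools and without each library, within 1.5 times for counts. Of 3748 values of named genes under alternatives, 3735 stayed on their side of the threshold, 13 lost it and 0 reversed. Of 715 list values, which hold the estimated correlation for the minor intron list only, 690 stayed, 16 lost and 9 gained a call. Thresholds moved the number of called genes by construction. With at least 1.5-fold it was 5288 (2588 higher, 2700 lower), with at least 2-fold 2077 (809 higher, 1268 lower), and against a 1.5-fold change 3164 (1400 higher, 1764 lower). With an estimated correlation 0 lists passed in camera, so all 26 calls were lost (4 at an unadjusted p under 0.05). Fry, which does not compare a list with other genes, passed 43 lists. The minor intron list, median 0.228, lost its call in camera with the estimated correlation at adjusted p = 0.319. Its range over the other alternatives was 1.16e-08 to 0.0108. For calls of at least 2-fold the excess on chromosome 7 was 3.15 percentage points and within 10 Mb 6.83, both past the threshold; the cause was not tested. Leaving out 1 library gave 15829 to 16056 called genes, 24 to 26 lists, a PDCD7 change of 0.42 to 0.49 and a minor intron median of 0.22 to 0.26. DESeq2 called 15325 genes, with no adjusted p for 2302. The scalings moved the median of all genes by at most 0.08.

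With the replicate number as a block (replicate block) 16460 genes were called, 16333 of them also called without it. Replicates of the same number deviated together with correlations of 0.021, -0.041 and -0.002, so no shared variation was seen. With 3 libraries per group this cannot show whether libraries of the same number share a clutch or a day. No mutant library correlated best with the sibling library of its own number. The fit with splice-site motifs was not run, since no genome was used here.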

Other observations

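The snRNA, Integrator, exosome, replicate 2 and digestive organ and eye tests and the reading of the splits for called genes were chosen after the results were seen, and the other tests below before theirs.

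Sm-class snRNAs, those of the spliceosomes and U7, which RNA polymerase II makes and which carry no poly(A) tail, had reads almost only in the mutant libraries. Summed over 235 genes, 44 of them with counts, they held 2068, 1962 and 2321 counts in mutants and 50, 49 and 69 in siblings, 35.0-fold more by CPM (25.5 ± 1.4 against 0.728 ± 0.13, n = 3). Of 17 tested, 16 rose and 0 fell. U2 genes were 109-fold, U1 genes 46.0-fold, U5 genes 13.7-fold and U4 genes 10.6-fold higher. Among RNAs of the minor spliceosome, U12 had 56 counts in mutants and 2 in siblings. U4atac had 710 and 0, at least 218-fold more against a floor of 3 counts over the group, and U11 82 and 0, at least 25.2-fold. U7, which processes histone mRNA, had 143 and 0, at least 44.0-fold. SNORA63 (ENSDARG00000115262) and the unnamed ENSDARG00000080450 behaved alike, with 370 against 8 and 1813 against 16 counts. Most are multicopy genes, so counts per copy are uncertain.

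Subunits of the 2 complexes that trim such RNAs were looked up afterwards. Of 16 Integrator genes 13 rose and 2 fell, INTS4 by log2 0.95 ± 0.04 SE and INTS7 by -0.37 ± 0.04. Of 12 exosome genes 9 rose and 2 fell, EXOSC5 by 1.76 ± 0.05, EXOSC2 by 1.61 ± 0.06 and EXOSC1 by -0.94 ± 0.04. The lists of minor intron genes hold INTS4, INTS7, INTS10 and EXOSC2. The gene ice1, whose complex acts at snRNA genes, rose 5.42-fold.

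Several technical sources could give snRNA reads in mutant libraries. Weaker selection of poly(A) RNA would raise RNA polymerase III RNAs as well, but their sum changed by log2 0.12, at most 0.29 in any pair of libraries, against 5.13 for the Sm-class snRNAs. Its members went both ways, 5S rRNA at 0.837-fold, 7SK at 1.54-fold (pairs up to log2 0.90), 7SL at 1.41-fold (pairs up to 1.04) and U6 at 3.17-fold on 61 and 18 counts, and replication-dependent histones rose 1.90-fold. These rises leave room for a small part from selection, not for the whole. Genomic DNA would raise other short genes, whose sum changed by log2 0.56, from 99.3 ± 6.4 CPM in siblings to 147 ± 4.8 in mutants. That sum includes SNORA63 and ENSDARG00000080450, which behaved like the snRNAs and held 1.48 and 7.27 CPM in mutants. Genomic DNA adds reads by amount, and the snRNAs started from only 0.728 CPM, so the ratio of these sums cannot decide for or against it. By amount, the 2337 RNA polymerase III genes held 103 ± 5.9 CPM in mutants and 95.5 ± 6.8 in siblings. The 303 U6 genes among them held 0.25 ± 0.13 and 0.0789 ± 0.029, while 7SK and 7SL rose. Genomic DNA would add to all these genes, so the values argue against it as the source of most snRNA reads. The rise of the other short genes leaves room for a part from it. Variants linked to the mutation that act only on nearby genes would keep the rise to chromosome 7, while called snRNA genes lay on 11 other chromosomes and 3 on chromosome 7. Whether a linked variant acts on snRNAs of other chromosomes was not tested. A candidate explanation, as a hypothesis, is unprocessed snRNA that gained a poly(A) tail in mutants. Lower mRNA of an Integrator subunit stays open as its source, since the lowest, INTS7, stood at log2 -0.371 and was called, and read ends were not analysed here. Exosome subunits, of which 9 rose and 2 fell, with EXOSC1 lowest at log2 -0.94, were not weighed as a source.

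The rise of minor intron genes was set against properties of the genes. Among 10000 random lists matched on mean expression and number of exon blocks, the list's median of 0.228 lay at percentile 100, with the middle 95% of random medians between -0.097 and 0.077. This argues against these 2 properties as the source. Without the 3 members that are also on other lists the median was 0.223, which decides nothing, since dropping any 3 members leaves at least 0.218. That the rise may follow from loss of the minor spliceosome remains a hypothesis, since intron reads were not counted and the annotation of these introns was not checked.

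Mutant replicate 2 held more of the fallen transcripts than the other mutant libraries. Of genes at least 4-fold lower in mutants with at least 5 CPM in siblings, the 41 lens genes exceeded the other mutant libraries by a median of 3.43% of the sibling level. The 164 genes outside the lens list exceeded them by 3.30% (middle 50%, 1.67% to 4.52%). A candidate explanation is about that share of wild-type material in mutant replicate 2, from a sibling larva or from carry-over between libraries. The cutoffs were set after the values were seen and no others were run. A milder phenotype in part of that pool would give such values too and stays open. Without mutant replicate 2, 15863 genes were called and the lens median was -4.03.

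A further pattern, the lower transcripts of digestive organs and eye, was tested after it was seen and then left out of the patterns weighed. Its values were a lens median of at most -3.77 under the 4 scalings, and a fast muscle median of 0.00 beside -0.94 for hepatocyte genes.

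In the split by genotype 16696 genes were called, and 1 of 10 splits reached that. The highest other called 0 (84 to 140 genes at unadjusted p under 0.05 in edgeR). For lists 1 of 10 splits reached 26, the highest other giving 25. Each other split still parts the genotypes 2 to 1, and whether that gives those lists was not tested. For the minor intron median 1 of 10 splits reached 0.228, the highest other being 0.094. With 10 splits a share under 0.05 cannot be had.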
